A study of Mus musculus with 9 samples.

How the data were processed

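Gene expression was measured by RNA sequencing in the gastrocnemius muscle of female mice. The 9 libraries fall into 3 groups of 3: young mice given vehicle, aged mice given vehicle and aged mice given ginkgolide B (GB). Per the labels, the vehicle was saline, GB was given at 12 mg per kg, and the daily oral gavage lasted 2 months. Ginkgolide B is a terpene lactone of the ginkgo tree and an antagonist of the platelet activating factor receptor. Per the labels' protocols, RNA was purified with TRIzol and chloroform, and libraries were made from total RNA with a KAPA mRNA kit. Groups and replicate numbers were taken from the sample titles. The vehicle titles hold 3M for young and 23M for aged mice, and the GB titles hold no such value. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical.

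The deposited table holds raw counts per gene, as whole numbers, for 56791 genes in the 9 libraries, with a gene length column. The submitters' processing notes name FastQC, HISAT2, SAMtools and DESeq2 without versions. They name 2 genome builds, GRCm39 and mm10. The read counter, the gene annotation and the use of strand are not given in the sources used here, and no coordinates are printed. Reads shared between near-identical copies may have been split or lost in counting. Values of the myosin heavy chain genes Myh1, Myh2 and Myh4, the alpha globin gene Hba-a1, ribosomal protein genes with pseudogenes and mitochondrial genes with nuclear copies are therefore uncertain, as are values of genes that overlap others.

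Counts were tested with edgeR 4.0.16 in R 4.3.3 on the values as deposited. Genes were kept with filterByExpr (minimum count 10, minimum total count 15), which left 17534 genes. Libraries were scaled with TMM factors, and 1 quasi-likelihood model with a mean per group and robust=TRUE was fitted to all 9 libraries. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested, and genes with an adjusted p under 0.05 were called. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. Levels are TMM-scaled CPM (counts relative to library size), given as mean ± SD over 3 libraries. Where a group had a count of 0, a limit of 3 counts over the group was used, which covers counting error only.

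Before the data were examined, 40 gene lists were fixed for muscle fibre types, muscle wasting, other cell types of the tissue, metabolism, signalling and stress. The 39 lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists within a comparison. The genes to be named followed a rule fixed at the same time. In each of the 2 comparisons of the series design, it took the 6 largest rises and the 6 largest falls among called genes with a mean of at least 2 CPM in the higher group and no overlap between the libraries. Symbols made of a predicted-gene number or a clone name were left out. The rule added up to 4 members of each called list, up to 2 members of other lists, and 10 genes whatever their values (Myh4, Myh7, Runx1, Cdkn1a, Cdkn2a, Ptafr, Mstn, Chrng, Col1a1 and Ppargc1a). Genes named outside this rule were chosen after their values were seen: Actc1, Hoxd8, Hoxd9, Six2, Dbp, Per1, Arntl and Gm56561. Some genes that the rule took are not reported here.

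Alternatives fixed beforehand were other scalings, other filters on low counts, DESeq2 1.42.0, limma-voom, robust=FALSE, fits of only the groups compared, the replicate number as a block, other thresholds, other set tests and leaving out each library. Added after seeing the data were offsets for gene length and for length with GC content, and, for single genes, library totals and upper-quartile factors. The offsets were each library's lowess trend (span 0.3). GC content came from the reference transcripts, matched by symbol, and was known for 95.2% of the genes tested.

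The procedure was tested on simulated counts for aged against young vehicle, with 200 of 17165 genes changed by known folds. It recovered 16.4% of the 1.5-fold, 50.7% of the 2-fold and 68.2% of the 4-fold changes, and of its 100 calls 6 were in an implanted list of 30 genes and 4 were false. The criterion set first, recovery of 80% of the 4-fold changes, was missed. After that run it was replaced, on the same simulated counts, by criteria on bias, sign, false calls and recovery among genes of at least 2 CPM. At that level 23.4% of the 1.5-fold, 82.9% of the 2-fold and 100% of the 4-fold changes were recovered, and below it 25% of the 4-fold changes were.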

Results

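The transcriptome of the gastrocnemius, a calf muscle made mostly of fast fibres, was compared between 3 young vehicle, 3 aged vehicle and 3 aged GB libraries of female mice. Total counts were 51543383 to 61680520 in the 6 vehicle libraries and 39478427 to 44294097 in the GB libraries. Replicates within each group differed by more than sampling noise, and each was used as a separate library.

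The GB libraries stood apart from the vehicle libraries. The first principal component held 57% of the variance and separated GB from vehicle, and the second held 11.7% and separated young from aged vehicle. Genes with a count numbered 18678 to 19362 in the GB libraries and 22616 to 24185 in the vehicle libraries. The 50 most abundant genes took 53.5 to 56.6% of counts with GB and 41.2 to 43.2% with vehicle. Mitochondrially encoded genes took 24.3 to 26.1% with GB, 13.9 to 15.3% in aged vehicle and 8.6 to 10.2% in young vehicle libraries. Mitochondrial ribosomal RNA took 1.06 to 1.59%, 0.28 to 0.41% and 0.09 to 0.14% in the same order. The labels give no batch, and every GB library is a treated one, so preparation and treatment cannot be told apart.

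**Figure D1:**
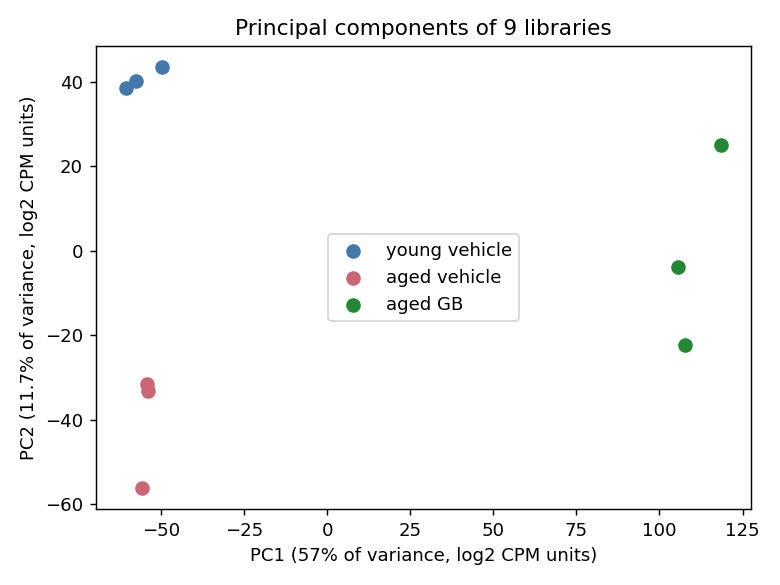
Principal components of log2 CPM over the genes tested, with 1 point per library coloured by group. The first component (57% of the variance) separates the 3 GB libraries from the 6 vehicle libraries, and the second (11.7%) separates young from aged vehicle.

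The first comparison of the series design asked how aged muscle differs from young muscle under vehicle. Slow fibre genes fell at 10 of 15 members with age, in a list that camera called with its preset correlation and not with an estimated one (adjusted p = 0.118 with an estimated correlation). Myh7, the slow myosin heavy chain, was at 432 ± 131 CPM in young and 3.82 ± 1.65 CPM in aged vehicle libraries (SD over 3 libraries each), a log2 fold change of -6.82 (SE 0.44, edgeR adjusted p = 0.000127). Myl2, the slow myosin regulatory light chain, had a log2 fold change of -6.21 (SE 0.46), and -6.94 without aged replicate 2, and the slow troponin genes Tnnc1, Tnnt1 and Tnni1 had -5.20, -4.98 and -4.52. In edgeR's quasi-likelihood test, genes differing between aged vehicle and young vehicle numbered 1508 of 17534, of which 757 rose and 751 fell. The number was 749 without young replicate 3, 866 without young replicate 2, 823 without aged replicate 3 and 935 without aged replicate 2. Of 107 called named genes, 74 were called without each library in turn.

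The slow fibre, fast fibre and excitation contraction coupling lists were called lower with age. Of 15 slow fibre genes 10 fell and 0 rose (camera adjusted p = 2.19e-12, and adjusted p = 0.118 with an estimated correlation), and 10 were lower adjusted over the list alone. Of 14 type IIb and fast glycolytic fibre genes 6 fell and 0 rose (camera adjusted p = 8.29e-05, and adjusted p = 0.432 with an estimated correlation), with 7 lower and 1 higher adjusted over the list alone. Among them Myh4, the type IIb myosin heavy chain, fell by 0.71 (SE 0.12) on the log2 scale, and Actn3, a Z-disc protein of fast fibres, fell by 0.57 (SE 0.11). The list of IIa and IIx fibres held 2 genes and was not tested. Myh1, the IIx heavy chain, rose by 1.76 (SE 0.15) and Myh2, the IIa heavy chain, fell by 1.74 (SE 0.28). Of 24 excitation contraction coupling genes 8 fell and 0 rose (camera adjusted p = 2.05e-05, and adjusted p = 0.399 with an estimated correlation), with 14 lower and 1 higher adjusted over the list alone. Jph2, which holds the junction of T-tubule and sarcoplasmic reticulum, fell by 0.92 (SE 0.10).

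Among the largest age changes that the naming rule took were the developmental transcription factor genes Hoxd10, Sim1 and Tbx1. Hoxd10 had a log2 fold change of -5.17 with age (SE 0.45), and -6.13 without aged replicate 3. Of 54 position genes, in a list drawn up after the values were seen, 3 rose and 8 fell with age, and 15 rose and 9 fell with GB. Hoxd8, Hoxd9 and Six2 were chosen after their values were seen. Hoxd8 was at 46.9 ± 3.39 CPM in young, 4.20 ± 0.550 CPM in aged vehicle and 47.7 ± 2.70 CPM in GB libraries. Hoxd9 was at 22.6 ± 1.59, 1.28 ± 0.0830 and 32.6 ± 5.11 CPM in the same order, and Six2 at 14.4 ± 0.427, 1.40 ± 0.228 and 12.5 ± 1.69 CPM. Sim1 and Tbx1 rose by 4.54 (SE 0.61) and 3.30 (SE 0.38). Tbx1 was at 9.27 ± 4.64, 91.0 ± 4.90 and 17.6 ± 2.46 CPM.

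**Figure D2:**
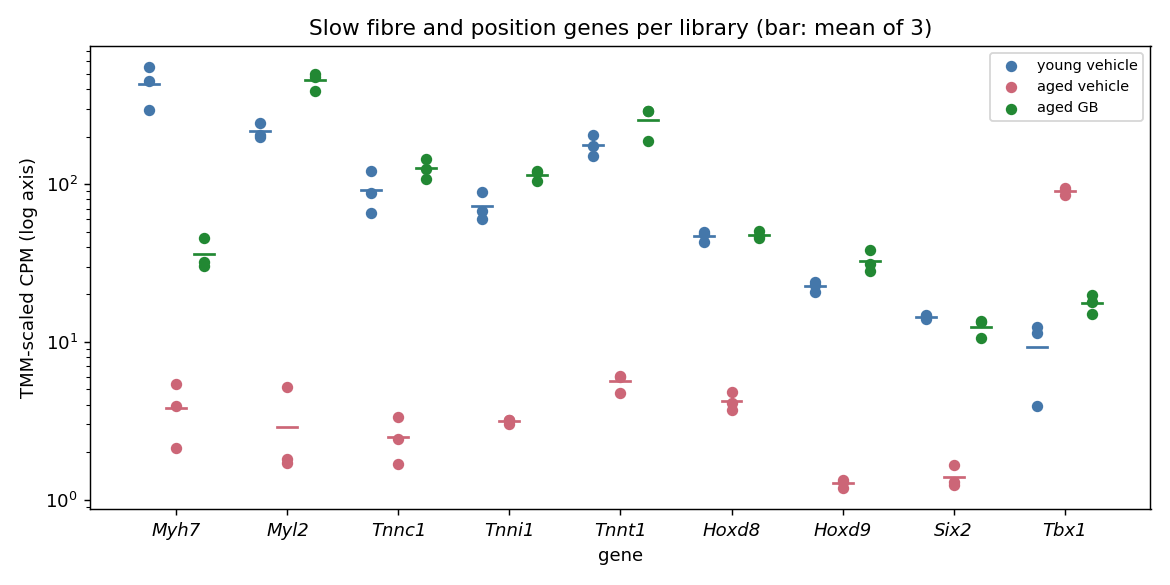
TMM-scaled CPM on a log axis for slow fibre genes (Myh7, Myl2, Tnnc1, Tnni1, Tnnt1) and position genes (Hoxd8, Hoxd9, Six2, Tbx1), with 1 point per library and a bar at the mean of 3. The aged vehicle libraries lie below the other groups for each gene except Tbx1, for which they lie above.

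The lists of energy metabolism, except glycolysis, were called higher with age. Mitochondrial ribosomal RNA took 0.28 to 0.41% of counts in aged and 0.09 to 0.14% in young vehicle libraries. Of 79 nuclear oxidative phosphorylation genes 24 rose and 0 fell (camera adjusted p = 2.93e-15, and adjusted p = 0.432 with an estimated correlation), with 49 higher adjusted over the list alone. Cox7a1 and Cox6c, subunits of cytochrome c oxidase, rose by 0.83 (SE 0.11) and 0.56 (SE 0.07). Of 13 mitochondrially encoded genes 9 rose and 0 fell (camera adjusted p = 6.38e-09, and adjusted p = 0.391 with an estimated correlation), with 12 higher adjusted over the list alone. One of them, mt-Nd1, rose by 0.78 (SE 0.10). Of 24 tricarboxylic acid cycle genes 4 rose and 1 fell (camera adjusted p = 0.000187, and adjusted p = 0.46 with an estimated correlation), with 11 higher and 1 lower adjusted over the list alone. Of 33 fatty acid uptake and oxidation genes 4 rose and 1 fell (camera adjusted p = 0.00691, and adjusted p = 0.495 with an estimated correlation), with 8 higher and 1 lower adjusted over the list alone. Fry did not call this list (adjusted p = 0.068, and 0.000801 to 0.495 over the alternatives). Ppargc1a, a coactivator of mitochondrial gene expression, rose by 0.69 (SE 0.16, adjusted p = 0.02). The Ppargc1a call was lost without young replicate 2 (adjusted p = 0.091), aged replicate 2 (adjusted p = 0.0788) or aged replicate 3 (adjusted p = 0.0637), and its adjusted p over the alternatives was 0.000857 to 0.091.

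The blood vessel and red blood cell lists were also called higher. Of 21 endothelial markers 10 rose and 0 fell (camera adjusted p = 2.24e-09, and adjusted p = 0.134 with an estimated correlation), with 16 higher adjusted over the list alone. Flt1, a receptor of vascular endothelial growth factor, rose by 0.99 (SE 0.13) and the adhesion molecule gene Pecam1 rose by 0.66 (SE 0.09). Of 12 smooth muscle and pericyte markers 6 rose and 0 fell (camera adjusted p = 2.47e-06, and adjusted p = 0.391 with an estimated correlation), with 8 higher adjusted over the list alone. Myh11, the smooth muscle myosin heavy chain, was at 29.3 ± 4.27 CPM in young and 109 ± 2.85 CPM in aged vehicle libraries. Of 8 red blood cell markers 5 rose and 0 fell (camera adjusted p = 0.00115, and adjusted p = 0.399 with an estimated correlation), with 5 higher and 2 lower adjusted over the list alone. The alpha globin gene Hba-a1 rose by 1.99 (SE 0.29).

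The connective tissue, nerve sheath and skin lists were called lower. These are levels of markers in whole tissue, and the share of each tissue in a sample was not measured. Of 44 collagen and extracellular matrix genes 7 fell and 0 rose (camera adjusted p = 6.59e-05, and adjusted p = 0.495 with an estimated correlation), with 16 lower adjusted over the list alone. Fry did not call this list (adjusted p = 0.116, and 2.13e-09 to 0.495 over the alternatives). Of 13 tendon markers 6 fell and 0 rose (camera adjusted p = 0.000136, and adjusted p = 0.43 with an estimated correlation), with 6 lower adjusted over the list alone. Kera, a proteoglycan of tendon and cornea, was at 12.8 ± 5.21 CPM in young and 1.97 ± 0.298 CPM in aged vehicle libraries. Of 16 Schwann cell and myelin markers 5 fell and 0 rose (camera adjusted p = 0.000386, and adjusted p = 0.43 with an estimated correlation), with 7 lower adjusted over the list alone. Of 7 skin and keratinocyte markers 1 fell and 0 rose (camera adjusted p = 0.000653, and adjusted p = 0.432 with an estimated correlation), with 7 lower adjusted over the list alone. The marker that fell was the desmosome gene Dsp, at 5.15 ± 3.17 CPM in young and 0.0105 ± 0.0182 CPM in aged vehicle libraries. DESeq2 called 5 of the 7 skin markers with age and limma-voom called 0. Kera and Dsp were lower in young replicate 1 than in young replicates 2 and 3, with Kera at 6.83 CPM against 16.1 and 15.5 CPM and Dsp at 1.52 CPM against 7.39 and 6.53 CPM. Col1a1, the main chain of type I collagen, was at 369 ± 194 CPM in young and 65.9 ± 19.9 CPM in aged vehicle libraries (adjusted p = 0.0423). The Col1a1 call held without young replicate 1 (adjusted p = 0.0038). It was lost without young replicate 2 or 3 or aged replicate 1, 2 or 3 (adjusted p of 0.104 to 0.138) and with the replicate number as a block (adjusted p = 0.086), with a range of 3.44e-05 to 0.138 over the alternatives.

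The denervation, atrophy and autophagy lists were called higher, and the heat shock list lower. Of 24 denervation and acetylcholine receptor genes 5 rose and 0 fell (camera adjusted p = 0.00156, and adjusted p = 0.399 with an estimated correlation), with 10 higher and 1 lower adjusted over the list alone. Ankrd1, a stress-responsive ankyrin repeat protein of the sarcomere, rose by 2.48 (SE 0.24). Chrng, the fetal acetylcholine receptor subunit, rose from 0.0434 ± 0.0518 to 1.70 ± 0.860 CPM (adjusted p = 0.00963), a log2 fold change of 5.16, and 6.54 without young replicate 3. Of 40 atrophy and proteasome genes 8 rose and 0 fell (camera adjusted p = 4.33e-05, and adjusted p = 0.432 with an estimated correlation), with 11 higher adjusted over the list alone. Of 36 autophagy and lysosome genes 5 rose and 2 fell (camera adjusted p = 0.0282, and adjusted p = 0.434 with an estimated correlation), with 7 higher and 2 lower adjusted over the list alone. Foxo3, a transcription factor of muscle wasting, rose by 0.77 (SE 0.11). The autophagy and lysosome call was lost without aged replicate 1 (adjusted p = 0.129, and 0.0123 to 0.434 over the alternatives). Of 26 heat shock and chaperone genes 5 fell and 0 rose (camera adjusted p = 0.0282, and adjusted p = 0.46 with an estimated correlation), with 5 lower adjusted over the list alone. The heat shock call was lost without young replicate 1 (adjusted p = 0.102) or aged replicate 1 (adjusted p = 0.0985), with a range of 0.0131 to 0.46 over the alternatives. Cdkn1a, an inhibitor of the cell cycle, rose by 1.70 (SE 0.32), a call lost without young replicate 3 (adjusted p = 0.0611, and 0.000135 to 0.0611 over the alternatives).

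Some genes and lists were not called with age. Runx1, a transcription factor induced by denervation, had a log2 fold change of 1.07 (SE 0.33, edgeR adjusted p = 0.0685), and DESeq2 called it (adjusted p = 0.015, and 0.015 to 0.247 over the alternatives). Mstn, a brake on muscle growth, had -0.67 (SE 0.21, adjusted p = 0.0707) and was called by DESeq2 (adjusted p = 0.00882), with upper-quartile factors (0.0416), with the length and GC offset (0.0496) and without aged replicate 1 (0.0368), with a range of 0.00882 to 0.213 over the alternatives. Ptafr, the platelet activating factor receptor, had -0.65 (SE 0.31, adjusted p = 0.247). Cdkn2a, a senescence marker, had 0 to 4 counts in each vehicle library and was not tested. In the immune lists 3 of 22 macrophage markers rose, and 1 of 21 complement genes rose and 1 fell. Of 7 MHC class II genes 1 fell. Adipocyte markers fell at 4 of 16 members, fibroblast markers rose at 2 and fell at 2 of 19, and satellite cell genes rose at 2 and fell at 1 of 23. Senescence inhibitors rose at 2 and fell at 3 of 16, and secretory factors rose at 1 and fell at 3 of 32. Glycolysis genes rose at 4 and fell at 3 of 26, insulin and mTOR signalling genes rose at 2 and fell at 5 of 32, and antioxidant genes rose at 1 and fell at 1 of 31. Clock genes rose at 2 of 20, immediate early genes rose at 4 and fell at 1 of 25, and unfolded protein response genes rose at 1 and fell at 1 of 30. Ribosomal protein genes fell at 1 of 76. Median, mean and test differed in sign for senescence inhibitors, glycolysis, antioxidants, the unfolded protein response, platelet activating factor and insulin signalling.

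Several immune lists had 0 genes called with age by edgeR. At an unadjusted p under 0.05 edgeR gave 3 of 47 interferon response genes, 1 of 12 MHC class I genes, 1 of 6 neutrophil, 3 of 13 T and NK cell and 6 of 18 B cell markers, and 1 of 12 platelet activating factor genes. DESeq2 called 2, 1, 0, 2, 0 and 0 of them in the same order, and limma-voom called 0 in each. Camera called further lists when a library was left out. Without young replicate 1 these were MHC class I (adjusted p = 0.0205), adipocyte (0.0421), clock (0.00024) and immediate early genes (0.000631). Without young replicate 2 or 3 they were B cell (0.000983 and 0.00101), T and NK cell (0.00277 and 0.00175), MHC class II (0.0298 and 0.047) and complement genes (0.042 and 0.0225). Members of the B cell and T and NK cell lists were higher in young replicate 1, such as Blk at 5.57 CPM against 0.0868 and 0.173 CPM in replicates 2 and 3, and Cd3g at 1.05 CPM against 0.0694 and 0.0864 CPM. Without aged replicate 1 the further lists were macrophage (0.045) and complement genes (0.0133), without aged replicate 2 clock (0.0192) and B cell genes (0.0489), and without aged replicate 3 interferon (0.0312) and clock genes (0.0331). Library totals, the replicate block and camera on ranks also called B cell and T and NK cell genes, the block called clock genes, and the block, ranks and both offsets called complement genes. Fry called macrophage and satellite cell genes.

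The second comparison of the series design asked what GB changes in aged muscle. Ribosomal protein genes rose at 75 of 76 members, while fatty acid oxidation genes fell at 21 of 33 and tricarboxylic acid cycle genes at 16 of 24. Camera called these lists with its preset correlation and not with an estimated one (adjusted p = 0.726, 0.773 and 0.773 with an estimated correlation). Rps12, of the small ribosomal subunit, was at 98.6 ± 1.86 CPM in aged vehicle and 797 ± 40.5 CPM in GB libraries, a log2 fold change of 3.02 (SE 0.08, edgeR adjusted p = 2.04e-10). Acadvl, which starts the oxidation of very long chain fatty acids, fell from 193 ± 11.4 to 14.1 ± 1.26 CPM, and Pdha1, of the pyruvate dehydrogenase complex, fell from 466 ± 27.7 to 46.8 ± 1.08 CPM. Myl2, of slow fibres, was at 2.89 ± 1.96 CPM in aged vehicle and 455 ± 57.5 CPM in GB libraries. In edgeR's test, genes differing between aged GB and aged vehicle numbered 9326 of 17534, of which 4281 rose and 5045 fell. With library totals alone 2030 rose and 8421 fell, and the median log2 fold change of all genes moved from -0.05 to -0.62, so directions are relative to the TMM scale.

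Fold change followed gene length in this comparison. The median log2 fold change was 1.06 for the 532 genes of up to 500 bases and -0.67 for the 2606 genes over 8000 bases, by the length column of the table. Across genes, which are not independent replicates, Spearman's correlation of log2 fold change with length was -0.345, against 0.019 in the age comparison. With an offset for each library's length trend, an alternative chosen after seeing the data, 8199 genes were called, and 6330 of the 9326 were called in the same direction. Over all genes tested the offset turned the correlation with length to 0.108, so the trend was overcorrected on average. Single genes were moved by their listed length, and the column header says only length. With GB, Atp5l, listed at 6443 bases, went from 1.21 to 1.53, and Rps20, at 4080 bases, stayed at 2.85. Cox7a1, at 535 bases, went from 0.78 to -0.69. The offset was fitted without the genes of lowest expression and may correct single genes too little or too much.

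**Figure D3:**
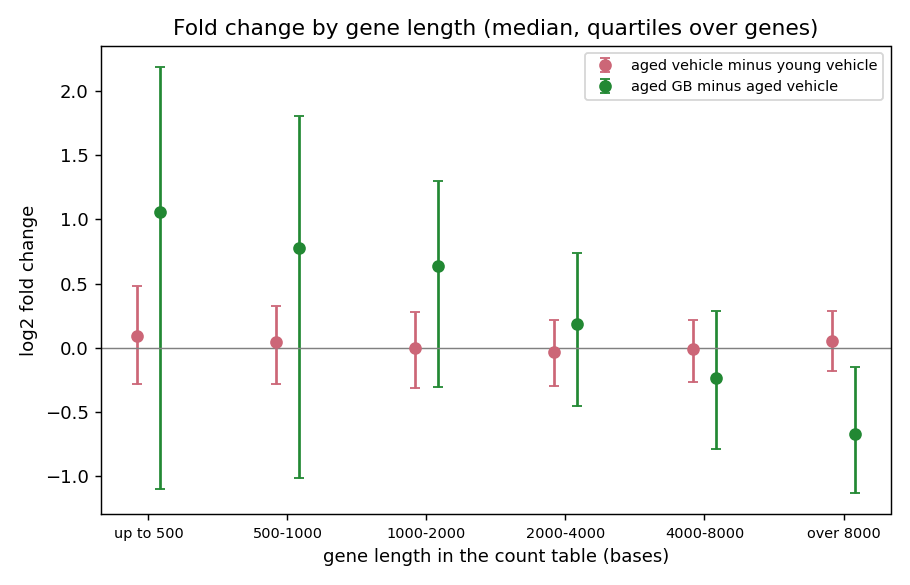
Median log2 fold change with quartiles over genes, by gene length in bases, for aged vehicle minus young vehicle and aged GB minus aged vehicle. The GB medians go from 1.06 in the shortest class to -0.67 in the longest, while the age medians stay within 0.1 of 0.

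The ribosomal, mitochondrial and antioxidant lists were called higher in the GB libraries. In these libraries the 50 most abundant genes took 53.5 to 56.6% and mitochondrial ribosomal RNA 1.06 to 1.59% of counts, against 41.6 to 42.3% and 0.28 to 0.41% in aged vehicle libraries. Of 76 ribosomal protein genes 75 rose and 0 fell (camera adjusted p = 5.39e-36, and adjusted p = 0.726 with an estimated correlation), with 75 higher adjusted over the list alone. Their median was 2.18, and 1.44 with the length offset. Of 79 nuclear oxidative phosphorylation genes 60 rose and 10 fell (camera adjusted p = 5.72e-11, and adjusted p = 0.773 with an estimated correlation), with 60 higher and 10 lower adjusted over the list alone. Of 13 mitochondrially encoded genes 11 rose and 0 fell (camera adjusted p = 2.73e-05, and adjusted p = 0.726 with an estimated correlation), with 12 higher adjusted over the list alone. One of them, mt-Nd1, rose by 1.83 (SE 0.10), and by 0.68 with the length offset. With the length offset, the nuclear and the mitochondrial list lost their calls (adjusted p = 0.265 and 0.132, and 1.11e-11 to 0.773 and 1.35e-07 to 0.726 over the alternatives) as their medians went from 0.92 to 0.11 and from 1.53 to 0.50. With the length offset 33 rose and 29 fell in the nuclear list, and 6 rose and 2 fell in the mitochondrial list. With library totals these medians were 0.35 and 0.96. Of 31 antioxidant genes 18 rose and 3 fell (camera adjusted p = 0.00172, and adjusted p = 0.726 with an estimated correlation), with 20 higher and 4 lower adjusted over the list alone. Gpx4, which reduces lipid peroxides, rose by 1.56 (SE 0.08), and by 0.84 with the length offset. The median of the antioxidant list was 0.53, and -0.04 with library totals, and its call was lost with the length offset (11 rose and 6 fell, median 0.25, adjusted p = 0.16, and 0.00015 to 0.726 over the alternatives).

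The lists of the tricarboxylic acid cycle, fatty acid oxidation, insulin signalling and matrix were called lower. Of 24 tricarboxylic acid cycle genes 16 fell and 1 rose (camera adjusted p = 0.000573, and adjusted p = 0.773 with an estimated correlation), with 17 lower and 1 higher adjusted over the list alone. Of 33 fatty acid uptake and oxidation genes 21 fell and 2 rose (camera adjusted p = 0.00172, and adjusted p = 0.773 with an estimated correlation), with 21 lower and 2 higher adjusted over the list alone. Ppara, a transcription factor of fat oxidation, fell by 5.64 (SE 0.37). Of 32 insulin, IGF and mTOR signalling genes 19 fell and 3 rose (camera adjusted p = 0.00485, and adjusted p = 0.773 with an estimated correlation), with 22 lower and 3 higher adjusted over the list alone. This call was lost with the length offset, where 6 rose and 11 fell, as the median went from -0.70 to -0.21 (adjusted p = 0.672, and 0.000372 to 0.773 over the alternatives). Of 44 collagen and extracellular matrix genes 26 fell and 1 rose (camera adjusted p = 0.000505, and adjusted p = 0.773 with an estimated correlation), with 26 lower and 1 higher adjusted over the list alone. Their median was -0.82, and -0.46 with the length offset, where 17 fell and 3 rose. With library totals the medians were -1.05 for the tricarboxylic acid cycle (TMM -0.48), -1.15 for fatty acid oxidation (TMM -0.59), -1.27 for insulin signalling and -1.39 for collagen. Col4a1, a chain of basement membrane collagen, fell by 1.66 (SE 0.11). Col1a1 fell by 1.57 (SE 0.55, adjusted p = 0.0486). The Col1a1 call held without GB replicate 1 (adjusted p = 0.0446) and was lost without GB replicate 2 or 3 or aged vehicle replicate 1, 2 or 3 (adjusted p of 0.0503 to 0.135). It was also lost with DESeq2 size factors, upper-quartile factors, the replicate block and both offsets, with a range of 0.00614 to 0.135 over the alternatives.

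Muscle fibre genes went in different directions. Of 15 slow fibre genes 10 rose and 1 fell (camera adjusted p = 0.000201, and adjusted p = 0.726 with an estimated correlation), with 10 higher and 1 lower adjusted over the list alone. Their median was 1.89, and 1.26 with the length offset, where 10 rose and 2 fell. Tnni1 rose by 5.19 (SE 0.15), Tnnt1 rose by 5.51 (SE 0.21) and Myh7 rose by 3.23 (SE 0.39), to 35.9 ± 8.20 CPM. Of 14 type IIb and fast glycolytic genes 7 rose and 3 fell (camera adjusted p = 0.023, and adjusted p = 0.784 with an estimated correlation), with 8 higher and 3 lower adjusted over the list alone. This call was lost with the length offset, as the median went from 0.69 to 0.43 (adjusted p = 0.323, and 0.000787 to 0.784 over the alternatives). With library totals the fast fibre median was 0.13 and the list stayed called (adjusted p = 0.0225). Mylpf, the fast myosin regulatory light chain, rose by 1.76 (SE 0.10), and by 0.68 with the length offset, while Myh1 fell by 4.20 (SE 0.17) and Myh2 fell by 2.17 (SE 0.29). Myh4 was not called (0.19, SE 0.12, adjusted p = 0.199). It was lower with library totals (-0.38, adjusted p = 0.00521), and higher with upper-quartile factors (adjusted p = 0.0402), with the length offset (0.00481), with length and GC (0.00648) and without aged vehicle replicate 1 (0.0171), with a range of 0.00481 to 0.606 over the alternatives. Of 16 Schwann cell and myelin markers 8 rose and 1 fell (camera adjusted p = 0.0184, and adjusted p = 0.773 with an estimated correlation), with 8 higher and 1 lower adjusted over the list alone. The Schwann cell median was 0.72, and 0.15 with library totals. Of 40 atrophy and proteasome genes 20 rose and 7 fell (camera adjusted p = 0.0184, and adjusted p = 0.784 with an estimated correlation), with 20 higher and 8 lower adjusted over the list alone. The median of the atrophy list was 0.37, and -0.20 with library totals, where the call was lost (adjusted p = 0.723), as it was with the length offset (14 rose and 11 fell, median 0.11, adjusted p = 0.587, and 0.00299 to 0.784 over the alternatives).

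The largest falls were in genes near or at 0 in GB libraries. Pdpr, the regulatory subunit of pyruvate dehydrogenase phosphatase, was at 162 ± 13.8 CPM in aged vehicle libraries, and with GB it fell by 6.75 (SE 0.19). Bmp5, a bone morphogenetic protein, fell by 6.51 (SE 0.50), and was at -7.78 without GB replicate 3. Pm20d2 fell by 6.32 (SE 0.43), and was at -6.97 without GB replicate 1. Lrtm2 and Pcdhgb6 had 0 counts in each GB library and were at least 127-fold and 98.1-fold lower than in aged vehicle libraries, with 3 counts over the group as the limit. Among genes with at least 5 counts in each vehicle library 207 had 0 in each GB library, and the reverse held for 1 gene, Gm56561. Whether these 0 counts reflect expression or processing was not tested. Rn7sk, a small nuclear RNA, rose by 5.32 (SE 0.79), by 4.29 without GB replicate 3 and by 3.65 with the length offset.

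Ptafr was at 2.41 ± 0.288 CPM in aged vehicle and 1.31 ± 0.594 CPM in GB libraries and fell by 0.87 (SE 0.33, adjusted p = 0.0401). The Ptafr call was lost without aged vehicle replicate 2 (adjusted p = 0.0877) or 3 (0.109), without GB replicate 1 (0.064) or 3 (0.105), with upper-quartile factors (0.0645) and with the replicate block (0.0535), with a range of 0.00223 to 0.109 over the alternatives. Of 12 platelet activating factor genes 2 rose and 3 fell, and the list was not called (camera adjusted p = 0.883) except by fry (adjusted p = 0.00446). Mstn rose by 0.87 (SE 0.21, adjusted p = 0.00453), a call lost with library totals (adjusted p = 0.183) with the length offset (0.0709) and with length and GC (0.141), with a range of 5.51e-05 to 0.183 over the alternatives. Ppargc1a fell by 0.82 (SE 0.16), and was at -0.49 with the length offset. Cdkn1a (-0.43, SE 0.31, adjusted p = 0.279) was not called, except with library totals (adjusted p = 0.0125, and 0.0125 to 0.721 over the alternatives), and was at 0.07 without aged vehicle replicate 1. Runx1 (-0.23, SE 0.33, adjusted p = 0.591) was not called, except without GB replicate 1 (adjusted p = 0.0297, and 0.0297 to 0.992 over the alternatives), and was at 0.48 with the length offset. Chrng (-0.72, SE 0.80, adjusted p = 0.478) was not called, and Cdkn2a, with 4, 24 and 1 counts in GB replicates 1, 2 and 3, was not tested.

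Other lists were not called with GB. Autophagy genes rose at 9 and fell at 11 of 36, denervation genes rose at 7 and fell at 5 of 24, and satellite cell genes rose at 5 and fell at 7 of 23. Excitation contraction coupling genes rose at 8 and fell at 13 of 24. Endothelial markers rose at 5 and fell at 9 of 21, smooth muscle markers rose at 2 and fell at 7 of 12, and red blood cell markers fell at 5 of 8. Tendon markers rose at 1 and fell at 8 of 13, fibroblast markers rose at 9 and fell at 5 of 19. Of 7 skin markers 0 were called by edgeR, DESeq2 or limma-voom, with 0 at an unadjusted p under 0.05 in edgeR. Senescence inhibitors rose at 5 and fell at 2 of 16, and secretory factors rose at 3 and fell at 10 of 32. Glycolysis genes rose at 10 and fell at 9 of 26, heat shock genes rose at 10 and fell at 6 of 26, and unfolded protein response genes rose at 10 and fell at 7 of 30. Clock genes rose at 1 and fell at 4 of 20, and immediate early genes rose at 7 and fell at 2 of 25. Complement genes rose at 4 and fell at 4 of 21, MHC class I genes rose at 3 and fell at 2 of 12, and MHC class II genes rose at 1 of 7. Neutrophil markers fell at 1 of 6, T and NK cell markers rose at 3 of 13, and B cell markers rose at 2 and fell at 1 of 18. Median, mean and test differed in sign for denervation, secretory factors, MHC class I, complement, neutrophils, satellite cells, glycolysis and excitation contraction coupling. With the length offset several of these counts changed, as the complement list had 1 that rose and 8 that fell, with a median of -0.35 in place of -0.02. Under that offset the unfolded protein response list had 5 and 7, denervation 3 and 4, satellite cell 3 and 6, MHC class I 1 and 1, and smooth muscle 0 and 7 genes that rose and fell. In the same order the immediate early list had 4 and 2, the clock list 2 and 2, the T and NK cell list 1 and 0, and the B cell list 0 and 2. With the length offset camera also called tendon (adjusted p = 0.042) and red blood cell markers (0.022), and with library totals T and NK cell (0.0144) and B cell markers (0.0251). Fry, which does not compare a list with other genes, also called the macrophage, adipocyte, tendon, endothelial, smooth muscle, red blood cell, platelet activating factor, unfolded protein response and both senescence lists.

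The third comparison set GB against young vehicle libraries, to see where GB libraries lay relative to young muscle. Hoxd8 (log2 fold change 0.02, SE 0.11, edgeR adjusted p = 0.866) and Tnnc1 (0.45, SE 0.26, adjusted p = 0.17) were not called different from young, while Myl2 (1.08, SE 0.36, adjusted p = 0.0362), Tnni1 (0.66, SE 0.13, adjusted p = 0.000748), Tnnt1 (0.53, SE 0.17, adjusted p = 0.0232) and Hoxd10 (0.97, SE 0.33, adjusted p = 0.0269) were higher. With the length offset the calls of Myl2 (0.49, adjusted p = 0.296), Tnnt1 (0.05, adjusted p = 0.852) and Hoxd10 (0.29, adjusted p = 0.497) were lost, and Tnnc1 was at -0.67 (adjusted p = 0.0883). Myh7 was lower (-3.59, SE 0.38), as were the calcium pump gene Atp2a2 (-1.33, SE 0.14) and Actc1, the cardiac actin gene, chosen after its values were seen, at 927 ± 79.7 CPM in young, 66.0 ± 9.53 CPM in aged vehicle and 101 ± 4.37 CPM in GB libraries. Rps12 was higher (3.04, SE 0.08) and Acadvl was lower (-3.49, SE 0.10) than in young libraries. In edgeR's test, genes differing between aged GB and young vehicle numbered 9406, with 4323 higher and 5083 lower. With library totals alone 2117 were higher and 8530 lower.

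The age change and the GB change were set against each other gene by gene. Of the genes called with age, 371 rose with age and fell with GB, and 298 fell with age and rose with GB, among them Myl2, Tnni1 and Hoxd10. Another 171 rose in both comparisons and 222 fell in both. Lists of these sizes drawn independently would share 218, 183, 185 and 216 in the same order, which are not the values expected without an effect, since both comparisons use the aged vehicle libraries. The GB change had the opposite sign for 61.9% of the 1508 genes called with age. In 20 simulations with no effect 84.6 to 87.7% of signs were opposite over the 1508 genes with the smallest p with age in each. At most 3 genes were called with age in these simulations, so they give no values to set beside the shared counts. Their 1508 genes were picked on noise that the shared aged vehicle libraries carry into both changes, unlike the genes called in the data. The 61.9% therefore cannot be read as less opposition than without an effect. The covariance of the log2 fold changes across genes was -0.329, against -0.0985 simulated, a difference of -0.231. For the opposition of the age change and the GB change with each aged vehicle library used in a single comparison, 57.8 to 66.2% of signs were opposite. In 20 simulations of the same splits with no effect, run after the data were seen, 42.5 to 56.8% were opposite. Using each library once does not remove a difference common to all aged vehicle libraries, such as another region sampled. That would also give opposite signs, and the simulations hold no such difference. These values therefore do not show that GB reverses a change with age.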

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

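Chosen after seeing the data were the offsets for gene length and GC content and, for single genes, library totals and upper-quartile factors. The counts of genes differing between aged vehicle and young vehicle, genes differing between aged GB and aged vehicle, and genes differing between aged GB and young vehicle stayed within 1.5 times under the other scalings, filters, limma-voom, robust=FALSE, fits of the groups compared and the offsets. DESeq2 called 2308 genes with age in place of 1508, and the cause was not tested. By construction of the threshold, 2391 genes passed with age at an adjusted p under 0.10, and with a log2 fold change of at least 1 the counts were 524, 5003 and 5231 in the 3 comparisons. Leaving out 1 library gave 749 (without young replicate 3) to 1456 genes (without young replicate 1) with age, 866 without young replicate 2, 935 without aged replicate 2 and 823 without aged replicate 3. It gave 8217 to 9355 genes between GB and aged vehicle and 8117 to 9436 between GB and young. With an estimated inter-gene correlation, camera called 0 lists with age and 0 with GB, in place of 18 and 12, with 4 and 2 lists at an unadjusted p under 0.05. Fry, which does not compare a list with other genes, called 18 and 22, and camera on ranks 21 and 12. Leaving out 1 library gave 18 to 22 lists with age and 12 to 13 with GB. Single-gene values also turned sign. Myh4 with GB was -0.38 with library totals. B2m with GB, at 1.10 with TMM, was -0.12 with the length offset and -0.14 with length and GC, and was no longer called. Cox7a1, called higher with GB (0.78), was called lower with the length offset (-0.69). Cdkn1a and Runx1 with GB turned sign without a call. For the opposition of the age change and the GB change, 56.0 to 66.2% of signs were opposite over the alternatives run. This range pools fits that share the aged vehicle libraries with fits that use each once. Simulations with no effect gave 84.6 to 87.7% for shared and 42.5 to 56.8% for unshared libraries. The range for shared libraries comes from genes picked on shared noise, not from called genes, so it is no like-for-like reference. Deviations of same-numbered libraries correlated at -0.028 to 0.057 over all genes, so no pairing by number was seen there. A link confined to fewer genes is not excluded by this. Dbp was highest and Arntl lowest in replicate 1 of each group, while Per1 was lowest in GB replicate 1. With the replicate number as a block, 1312, 8958 and 9025 genes and 22 and 12 lists were called, and 61.7% of signs were opposite. Genes under 2 CPM were recovered less often in the simulated test, which was run at 1 depth.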

Other observations

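All tests of explanations in this part were chosen after the results were seen, and the length offset was an alternative added then. The interferon, macrophage and adipocyte lists were not called with GB, a comparison in which 9326 of 17534 genes were called. Of 47 interferon response genes 16 rose and 5 fell with GB (camera adjusted p = 0.103), with Psmb10, an immunoproteasome subunit, at 1.36 (SE 0.13) on the log2 scale and Ifi35 at 1.42 (SE 0.14), and 0.63 and 0.70 with the length offset. This list was called without aged vehicle replicate 3 (adjusted p = 0.0204) or GB replicate 2 (adjusted p = 0.042), with a range of 0.0204 to 0.912 over the alternatives. Of 22 macrophage markers 9 fell and 1 rose (camera adjusted p = 0.16), a list that was called with the length offset, where 15 fell and 0 rose (adjusted p = 0.00196, and 0.000207 to 0.726 over the alternatives). Adgre1, which encodes the F4/80 antigen, went from 6.33 ± 1.14 to 1.71 ± 0.167 CPM. Of 16 adipocyte markers 7 rose and 1 fell (camera adjusted p = 0.103), and Cidec, a lipid droplet protein, rose by 2.09 (SE 0.20), and by 1.34 with length and GC. The adipocyte list was called without GB replicate 3 (adjusted p = 0.0473, and 0.00809 to 0.773 over the alternatives).

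A broad difference set the GB libraries apart from the vehicle libraries. A smooth trend with listed gene length as the whole cause is argued against by the 8199 genes called with the length offset, 6330 of them in the same direction as without it. Over all genes the offset overcorrects the trend, which can add calls of its own, and several list calls ended there. Length bias that the listed length does not capture was not tested. Lower depth is argued against as the cause of the fewer detected genes, since vehicle libraries thinned to the depth of the shallowest GB library kept at least 22313 genes with a count, against at most 19315 in a GB library thinned alike. Separate preparation, sequencing or processing of the GB libraries may contribute and cannot be told apart from treatment, because every GB library is treated. Of the genes called against aged vehicle, 82.3% were called in the same direction against young vehicle, a share that the shared GB libraries raise and that separates neither explanation, and an effect of GB stays open and untested.

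In the aged vehicle libraries 10 of 15 slow fibre genes, Hoxd8, Hoxd9 and Six2 were lower and Tbx1 higher than in young, a set put together after the values were seen, while in GB libraries Hoxd9 was above young (0.53, SE 0.13, adjusted p = 0.00339) and Myh7 and Atp2a2 were below young (-3.59, SE 0.38, and -1.33, SE 0.14). A small slow-fibre part missing from the aged vehicle samples is argued against for Tbx1 alone, which rose by 3.3 (SE 0.38) with age, more than leaving out a small part can raise the rest. Another muscle or part of the muscle in the aged vehicle samples may account for the pattern, as Hoxd9 was at -4.14 with age, but the labels name the same muscle for every library and no region. A region sampled in that group cannot be told apart from the group itself, since every aged vehicle library was low. Age alone does not follow the pattern, as the GB libraries are aged too, and a change with age that GB reverses in part stays open and untested.

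Clock genes were apart in young vehicle replicate 1, and in part in aged vehicle replicate 1, with Per1 at 373 CPM against 127 and 129 in aged replicates 2 and 3, which was not tested further. In each group Dbp was highest and Arntl lowest in replicate 1, with Dbp at 52.0 CPM against 36.1 and 31.9 in GB libraries. Per1 and Per2 went the other way in GB replicate 1, at 76.9 CPM against 88.2 and 98.9 and at 24.2 CPM against 36.5 and 34.1. A link of clock genes with the replicate number was not tested. The log2 difference of young replicate 1 from replicates 2 and 3 had a median of 1.57 over 10 genes of the Per and Dbp arm and -0.64 over 5 genes of the Arntl arm, a gap of 2.2. Tissue taken at another time of day, in replicate 1 or in replicates 2 and 3, stays open as a candidate explanation, since the arms were drawn up after these genes were seen to be apart. For genes above 3 on the log2 CPM scale the median size of this difference was 0.89 for 13 of these 15 clock genes and 0.11 for 8147 other genes. The clock genes were grouped after they were seen to differ, so their larger size was fixed by that choice. The 0.11 argues only against a difference of like size across the other genes at that level. Young replicate 1 did differ in other genes, with a chi-square per gene of 60.4 and 50.6 against replicates 2 and 3 and 18.7 between those, and Col1a1 at 146 CPM against 457 and 505. In the other groups replicate 1 was apart too. Its chi-square values were 51.5 and 60.2 against 16.6 in aged vehicle, and 33.5 and 51.5 against 17.9 in GB libraries. With young replicates 2 and 3 alone as the young group, the log2 fold change with age was 2.35 for Dbp (adjusted p = 3.28e-05) and -1.80 for Arntl (adjusted p = 0.000421). With replicate 1 included neither was called (adjusted p = 0.904 and 0.167), and no biological explanation was tested.

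Each comparison allows 10 splits of its 6 libraries, too few for a share under 0.05, and 1 split, the real one, gave the largest count in each. The real split called 1508 genes with age and the highest other split 2. For GB against aged vehicle the values were 9326 and 0, and for GB against young vehicle 9406 and 0.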
